A study of Sus scrofa with 4 samples.

How the data were processed

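Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase cuts and tags open chromatin, in serum-starved porcine fetal fibroblasts (PFFs) from skin. Per the labels, 2 libraries came from wild-type cells with the vector pTK-642 (control 1 and control 4) and 2 from cells that over-expressed BRG1 from pTK-642-BRG1 (BRG1 1 and BRG1 4). The labels do not say whether libraries of a group came from separate cultures. The p-values of tests that compare libraries therefore measure only the spread between these samples, which may be technical. Tests that count regions or genes do not measure that spread. At most 0.202% of the intervals of any pair of libraries had the same start and end, so no list was a copy of another. This does not show separate cultures, and n counts the libraries the labels list.

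The authors deposited 1 peak list per library in the narrowPeak layout of MACS2. FastQC, BWA, Bowtie, SAMtools and MACS2 are named with no version, role or order, and the build Sscrofa11.1 is named, per the submitters' processing notes. The deposited fold is a ratio of the pileup at the summit to the background of the same library, computed by the authors. The deposited −log10 p-value and −log10 q-value were given by the authors' caller within each library, and the lowest −log10 q lay between 1.31 and 1.35, close to a q of 0.05. The deposited score is the whole part of the −log10 q-value multiplied by 10. The fold, p-value and score were used only to describe, rank or filter peaks within their own list. The shift of reads for the Tn5 cut, the handling of duplicate and mitochondrial reads and the settings of the caller are not given in the sources used here. Each of them can change how many peaks are called and how wide they are.

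Depth per library is not stated and was read from the peak lists in relative terms. In MACS2 the fold and the p-value at a summit together fix a whole-number pileup and a background, and at least 99.9989% of peaks in each list gave such a pair (tolerance 0.0001). The lowest background per library, which is proportional to depth, was 1.91 tags per 200 bp in control 1, 1.79 in control 4, 1.55 in BRG1 1 and 1.77 in BRG1 4. The backgrounds and the lowest peak width of 200 bp point to a tag extension of 200 bp in all 4 lists. Absolute depth is unknown, so no counting interval is given.

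Peaks of the 4 libraries were merged into union regions where they overlapped by at least 1 bp. A region was called BRG1-only when a peak of both BRG1 libraries and of neither control library overlapped it, and control-only in the opposite case. The same counts were made for the other 2 ways to split the 4 libraries into pairs. Jaccard indices are shared over total base pairs under peaks. Group means were compared by two-sided exact permutation tests, whose smallest p with 2 against 2 is 0.33. Shares of regions and genes were compared by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment, and BRG1-only against control-only gene counts by an exact binomial test. Regions and genes are not independent replicates, so those tests describe these 4 libraries.

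Gene positions came from a RefSeq gene table of the same build, which gives the start and end of each gene but no strand, exon or transcript. The planned promoter window around transcription starts was therefore replaced by a gene end, defined as within 1 kb of either end of 1 of 19550 protein-coding gene models on chromosomes 1 to 18, X and Y. Exonic, intronic and UTR positions could not be assigned. A summit inside a model and farther from its ends was called gene body, and a region over 10 kb from any gene end was called distal. Distal regions may therefore lie inside a gene model, and the gene-body and distal shares overlap. Of 362 genes on 18 fixed lists, 344 matched the table. A motif comparison of 28 motifs was planned and was not run, because no genome sequence was used here.

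Named genes followed a rule fixed before the data were examined, as were the lists, the tests and most other settings tried. For each direction it took the 10 protein-coding genes with a gene-end region of the highest mean percentile of −log10 p within each list, the 5 highest distal regions by nearest gene end, up to 12 list genes with such a region, and SMARCA4. Each region was assigned to its nearest gene end only, so another gene with an end near the same region was not named by the rule. Genes outside that rule were chosen after their values were seen, and the text says so in the paragraphs that name them. The test of how many list genes had a gene-end peak in all 4 libraries and the comparison of positions with lists of equal length were added after seeing the data.

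Other settings chosen before the data were examined were a −log10 q of at least 5, the same number of top peaks in every list (90851, or 45425), placed chromosomes only, overlap of 50% of the shorter interval or reciprocal overlap of 50%, a gene-end window of 3 kb, leaving out each library, and replicate number as a block. Thinning to the lowest depth was added after seeing the data. It drew pileups binomially 10 times and kept peaks with a −log10 p of at least 5, and the same minimum without thinning served as its reference. Enrichment at regions shared by all 4 libraries is the recovered pileup over the local background of the strongest peak, for peaks with a −log10 p under 250.

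The steps were run on simulated data to look for errors of calculation. From 26869 simulated regions, 200 of 200 planted BRG1-only and 400 of 400 planted control-only regions were found. Copies of a region differed between libraries only by trimmed edges and always overlapped, so this recovery was fixed in advance. Differences between libraries in depth, peak width and calls near the threshold were not simulated. The list test over 19550 genes called the 1 planted list and 0 others, and the pileup and background were recovered for 20000 of 20000 simulated peaks. Calculations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and bedtools 2.31.1, and figures were drawn with matplotlib 3.10.9.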

Results

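Chromatin accessibility was profiled by ATAC-seq in porcine fetal fibroblasts, the donor cells of somatic cell nuclear transfer, to ask how over-expression of BRG1 bears on chromatin openness. BRG1, encoded by SMARCA4, is an ATPase of the BAF chromatin remodelling complex. There were 2 BRG1 libraries (BRG1 1 and BRG1 4) and 2 vector control libraries (control 1 and control 4), all from serum-starved cells. Relative to control 1, depth was 93.5% in control 4, 81.2% in BRG1 1 and 92.6% in BRG1 4.

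The SMARCA4 locus was examined first, because it is the over-expressed gene. SMARCA4 lies on chromosome 2 from 69717175 to 69810301 (Sscrofa11.1) and held 4 peaks in each library. Its strongest peak by rank lay at the lower-coordinate end in all 4 libraries, from 69716520 to 69717913 in control 1, at percentiles of 94.5 in control 1, 93.7 in control 4, 94.6 in BRG1 1 and 92.4 in BRG1 4 of their own lists. A peak at the higher-coordinate end was called in control 1, control 4 and BRG1 1 and not in BRG1 4. BRG1 4 instead held a weak gene-body peak from 69723451 to 69723650, at percentile 1.79. Peaks do not measure expression, and exons were not annotated, so reads from the introduced BRG1 sequence could not be told from those of the native gene.

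**Figure D1:**
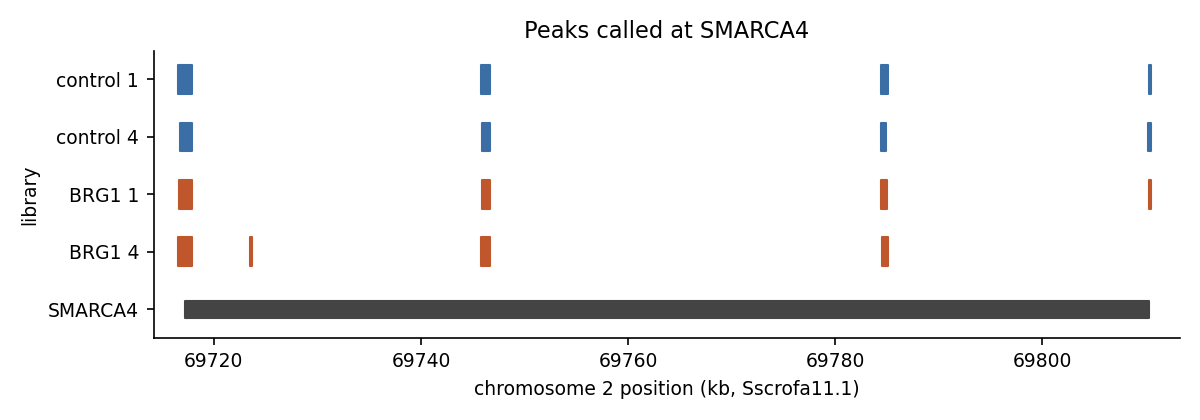
Peaks called at SMARCA4 in each library (bars, vertical axis) along chromosome 2 in kb, with the gene model in dark grey. Each library held 4 peaks, and the peak at the lower-coordinate end was called in all 4.

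The extent of open chromatin was compared next. Peaks numbered 107475 in control 1, 105954 in control 4, 96367 in BRG1 1 and 90851 in BRG1 4, with means of 93609 ± 3900 for BRG1 and 106714 ± 1076 for control (SD, n = 2 each, exact permutation p = 0.33). The BRG1 mean was 0.877 of the control mean, and both BRG1 libraries lay below both controls. The length under peaks did not follow this order, at 52.0 ± 5.11 Mb for BRG1 and 52.6 ± 1.33 Mb for control (SD, n = 2 each, exact permutation p = 1). BRG1 4 had the widest peaks, with a median width of 541 bp against 403 bp in control 1, 396 bp in control 4 and 404 bp in BRG1 1. With 2 libraries per group the smallest p that this exact permutation test can give is 0.33, so no group difference could pass 0.05 by it. The ratio of covered length was 0.989 and turned to 1.01 without control 1, to 1.06 without BRG1 1 and to 1.06 with lists of equal length.

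**Figure D2:**
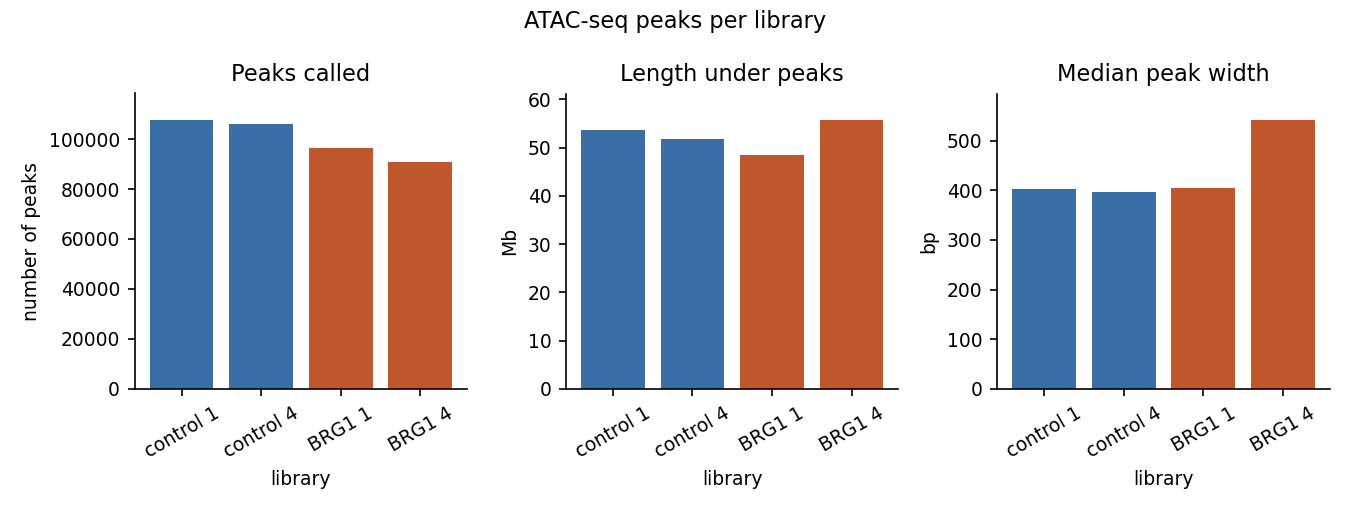
Number of peaks, length under peaks in Mb and median peak width in bp for each library (1 bar per library, controls in blue and BRG1 in orange). Both BRG1 libraries have fewer peaks than both controls, and BRG1 4 has the widest peaks at a median of 541 bp.

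Peaks at gene ends, gene bodies and elsewhere were compared to see where the called peaks lay. Gene ends held 14.7 ± 0.203% of BRG1 peaks and 13.6 ± 0.0836% of control peaks (SD, n = 2 each, exact permutation p = 0.33). Gene bodies held 43.6 ± 0.134% and 44.0 ± 0.0550%. On chromosome X, 2324.5 ± 115 peaks were called in BRG1 and 2746.5 ± 26.2 in control libraries (SD, n = 2 each, exact permutation p = 0.33). That ratio of 0.846 was near the 0.877 of all peaks, so most of the gap followed the total peak number. The gene-end difference of 1.09 percentage points turned to −0.0677 with lists of equal length.

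Most open regions were common to both groups. Of 121788 union regions, 75244 (61.8%) were called in all 4 libraries, 903 were BRG1-only and 5376 were control-only. Regions called in all 4 libraries had a median percentile of 60.6 within their lists, against 13.0 for BRG1-only and 16.5 for control-only regions, and 0 BRG1-only and 20 control-only regions ranked in the upper 50 percentiles. Other pairings of the libraries gave smaller counts than the control pair: 1904 regions were private to BRG1 1 with control 1 and 1205 to BRG1 4 with control 4, while 1782 were private to BRG1 1 with control 4 and 1513 to BRG1 4 with control 1. With lists of equal length there were 2245 BRG1-only and 2240 control-only regions, while the other pairings gave 1413 to 1632. Equal lengths hold the first 2 counts near each other by construction, so they do not test the excess of control-only regions. Leaving out control 1, control 4, BRG1 1 or BRG1 4, which lowers the number of libraries that must share a call, gave 2402, 2172, 5308 and 4042 BRG1-only and 11534, 12273, 13217 and 8890 control-only regions.

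**Figure D3:**
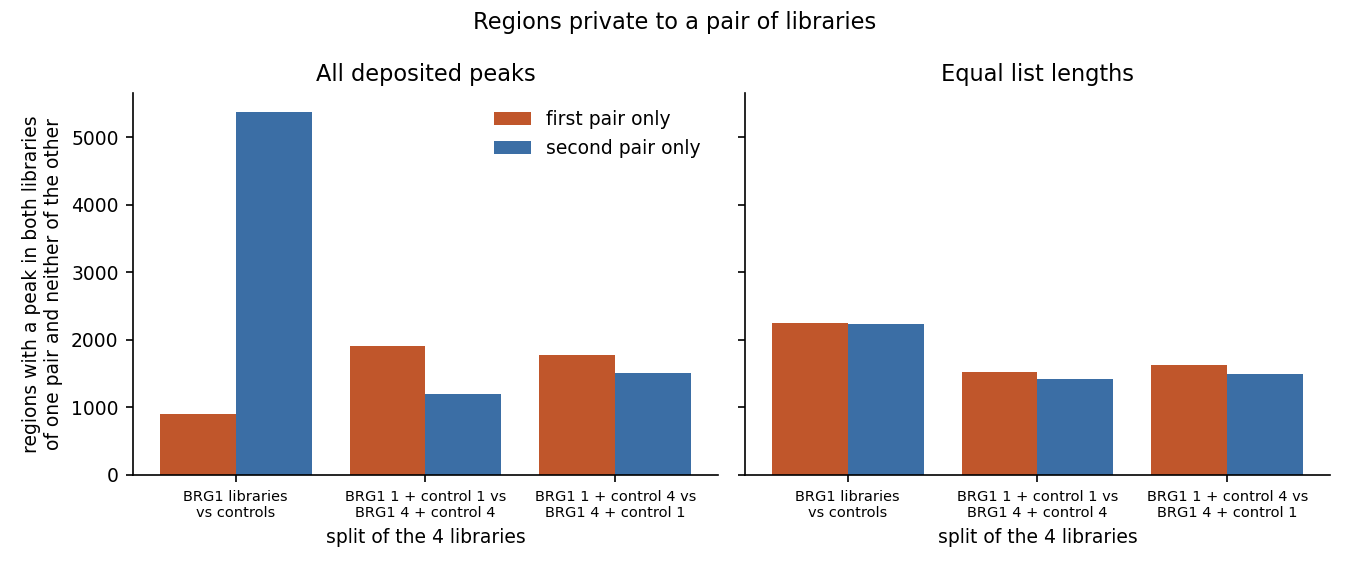
Number of regions with a peak in both libraries of a pair and in neither library of the other pair, for the 3 splits of the 4 libraries, with all deposited peaks and with lists of equal length. With all peaks the control pair has 5376 private regions and the BRG1 pair 903, and with equal lengths the counts are 2240 and 2245.

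Base pairs under peaks overlapped most between control 1 and control 4, with a Jaccard index of 0.736. BRG1 1 lay nearly as close to the controls (0.715 with control 1 and 0.719 with control 4) and BRG1 4 lay farther away (0.662 and 0.652), with 0.663 between BRG1 1 and BRG1 4. The mean within groups exceeded the mean between groups by 0.0123, against −0.0112 and −0.00110 for the other splits. The difference turned to −0.0225 without control 1 and −0.0260 without control 4.

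BRG1-only and control-only regions differed in position. Gene ends held 64 of 903 BRG1-only regions (7.09%) and 239 of 5376 control-only regions (4.45%), and 18.1% of regions called in all 4 libraries (Fisher's exact test of BRG1-only against control-only, odds ratio 1.64, adjusted p = 0.00154). Distal regions made up 68.3% of BRG1-only and 74.5% of control-only regions (Fisher's exact test, adjusted p = 0.000373), and gene bodies 47.6% and 47.5% (adjusted p = 0.943). Sets private to the pairs of the other splits had gene-end shares of 6.15% to 6.99% and distal shares of 68.6% to 70.9%, so that the BRG1-only set lay just outside both ranges on one side and the control-only set farther outside on the other. With lists of equal length the gene-end shares were 7.04% and 6.16% (Fisher's exact p = 0.253) and the distal shares turned to 72.5% and 69.9% (p = 0.0517), so neither difference was kept. Between chromosomes, no share differed after adjustment: the lowest adjusted p was 0.141, on chromosome 15, with 32 BRG1-only and 308 control-only regions.

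The 10 named BRG1-only regions at gene ends included those at IL6, a cytokine (chromosome 9, 91509993 to 91510276, inside the gene model and 554 bp from its higher-coordinate end), CXCL8, a chemokine (chromosome 8, 69936005 to 69936512, outside the model and 144 bp from its end), and IFNGR2, a subunit of the interferon gamma receptor. BICRA, a subunit of a BAF complex (chromosome 6, 53338158 to 53338429, 737 bp outside the lower-coordinate end), and NCAPD2, a condensin subunit, were also among the 10, with TULP3, RASL11A, SNX10, CLP1, an RNA kinase, and IFITM3, a restriction factor of viruses that belongs to a family of near-identical copies, so that its call is uncertain. The region at NCAPD2 (chromosome 5, 64135721 to 64136153) also lay within 1 kb of an end of GAPDH, a gene of the housekeeping list. The 5 distal BRG1-only regions are named by the nearest gene end only: SP3 at 31219 bp, CCL2 at 36603 bp, GINS2 at 47459 bp, ATP10D at 122361 bp and KLF4 at 480639 bp. The region named for GINS2 lay inside the model of GSE1, and that for ATP10D inside a gene model other than ATP10D. GAPDH and GSE1, outside the naming rule, were added for their position after the values were seen. The authors' fold of the peaks at the 10 gene-end regions ran from 2.04 to 5.99, and all 10 genes also had a gene-end peak in all 4 libraries. These 10 regions lay 152 to 3020 bp from the nearest region called in all 4 libraries, all but that at IL6 within 1 kb.

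Named control-only regions at gene ends lay beside TNFRSF12A, a receptor of the tumour necrosis factor family (chromosome 3, 39166063 to 39166302, across the lower-coordinate end of the model), and PLAU, which encodes urokinase (chromosome 14, 76630203 to 76630428, inside the model and 890 bp from its lower-coordinate end). The others were HAUS6 and CKAP2L, which encode spindle proteins, BCL6B, a transcriptional repressor, TNRC6B, of microRNA silencing, SUN2, of the nuclear envelope, MYL1, a myosin light chain, AMCF-II, a pig chemokine, and C14H10orf105. The 5 distal control-only regions were nearest to an end of TJP1 at 17846 bp, MYOM2 at 29946 bp, SYTL2 at 51100 bp, BCAT1 at 96287 bp and LSAMP at 186198 bp. Those of TJP1, MYOM2 and SYTL2 lay inside the models of these genes. The authors' fold at the 10 gene-end regions ran from 2.47 to 8.24, and 7 of the 10 genes had a gene-end peak in all 4 libraries, the exceptions being CKAP2L, MYL1 and C14H10orf105. These 10 regions lay 436 to 7131 bp from the nearest region called in all 4 libraries. With lists of equal length 616 of 903 BRG1-only regions (68.2%) and 1970 of 5376 control-only regions (36.6%) kept their call. The named regions, most of them picked for high rank, kept theirs except those at SOX18, UHRF2 and PAX7.

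**Figure D4:**
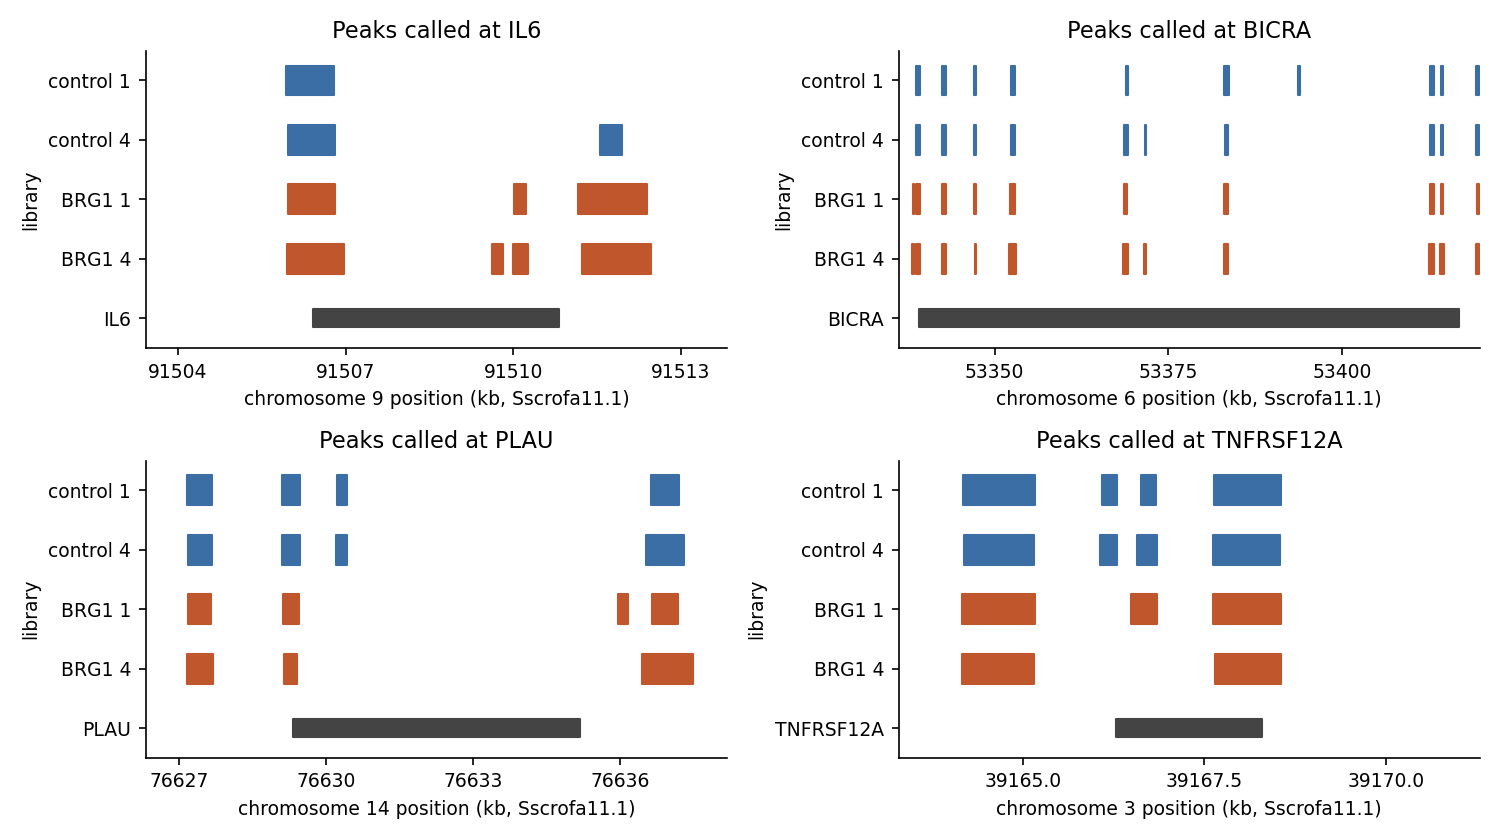
Peaks called in each library (bars, vertical axis) at IL6, BICRA, PLAU and TNFRSF12A along the chromosome in kb, with gene models in dark grey. The region from 91509993 to 91510276 at IL6 was called in both BRG1 libraries only, and that from 76630203 to 76630428 at PLAU in both control libraries only, beside peaks called in all 4 libraries.

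Gene ends of the chromatin and cell cycle lists were open in both groups. All 4 libraries had a gene-end peak at 25 of 27 BAF complex subunits (adjusted p = 0.0211 by Fisher's exact test against the other genes), 25 of 27 histone acetylation genes (adjusted p = 0.0211), 33 of 35 histone methylation genes (adjusted p = 0.00224), 34 of 36 cell cycle genes (adjusted p = 0.00210) and 12 of 12 housekeeping genes (adjusted p = 0.0383), against 13334 of 19550 genes (68.2%) in total. Single genes of the lists named in this paragraph were chosen after their values were seen. The exceptions among BAF subunits were BCL7B and BICRAL, with a gene-end peak in no library. Pluripotency genes were less often open, with 9 of 28 in all 4 libraries and 15 in none (Fisher's exact test, adjusted p = 0.00210). POU5F1, NANOG, LIN28A and SALL4 had no gene-end peak in any library, while the 9 with one in all 4 were SOX2, KLF2, KLF4, KLF5, TFCP2L1, TBX3, MYC, MYCN and FGF4. Fibroblast and matrix genes had 24 of 28 (Fisher's exact test, adjusted p = 0.106), and DCN, which encodes the matrix proteoglycan decorin, had no gene-end peak in any library. Serum response and AP-1 genes had 20 of 22 (Fisher's exact test, adjusted p = 0.0540), apoptosis genes 16 of 18 (adjusted p = 0.112), DNA methylation genes 12 of 18 (adjusted p = 1), imprinted genes 12 of 19 (adjusted p = 0.754) and early embryo lineage genes 10 of 20 (adjusted p = 0.129). Among markers of other cell types, keratinocyte, endothelial and muscle markers each had 3 of 9, melanocyte and glial markers 4 of 9, adipocyte markers 5 of 8 and immune cell markers 6 of 10, with adjusted p by Fisher's exact test from 0.0606 to 0.778.

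**Figure D5:**
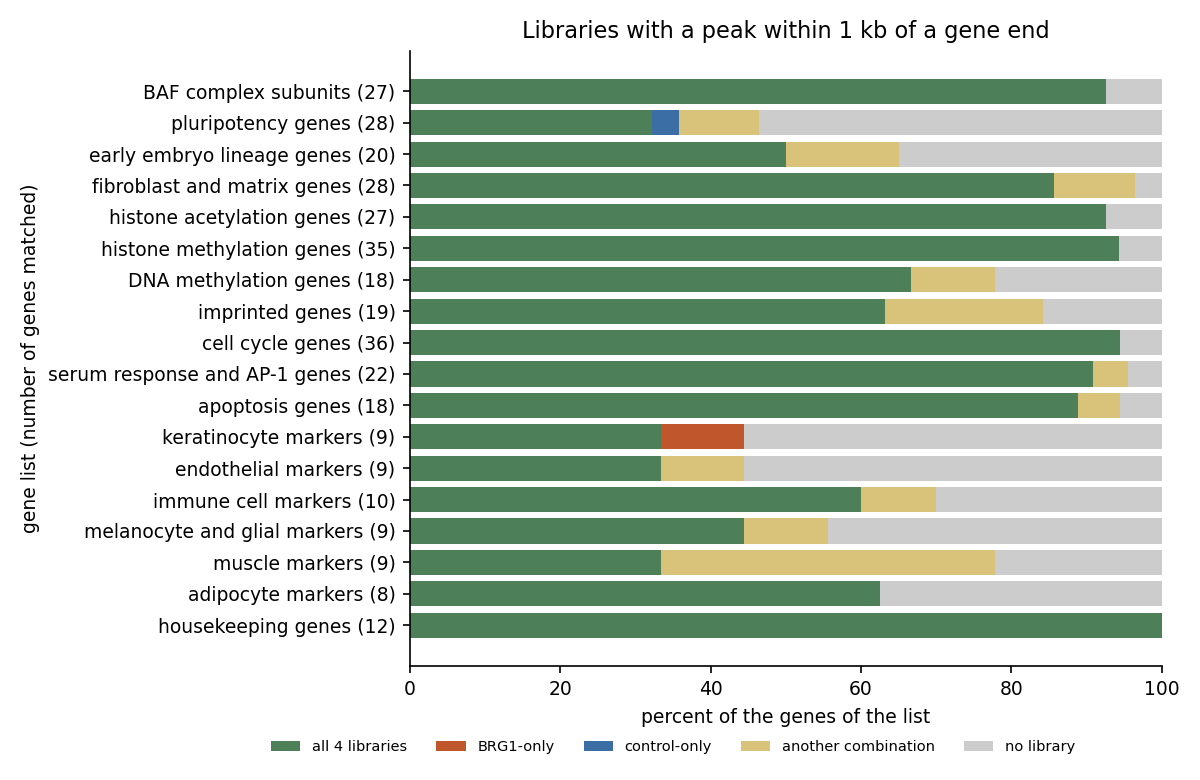
Percent of the genes of each fixed list (horizontal axis) with a peak within 1 kb of a gene end in all 4 libraries, in both BRG1 libraries only, in both control libraries only, in another combination or in no library. Housekeeping genes reach 12 of 12 in all 4 libraries and pluripotency genes 9 of 28.

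Few genes of the fixed lists differed between the groups, and such genes were few throughout, at 39 BRG1-only and 104 control-only of all 19550. No list passed the test for BRG1-only or control-only genes. Lists this short could hold few of them by share alone, so this does not show that the groups were alike there. The lowest adjusted p by Fisher's exact test was 0.321 (unadjusted p = 0.0178), for keratinocyte markers, where CLDN4, a tight junction protein, was the 1 BRG1-only gene of 9. In the pluripotency list TDGF1, a co-receptor of Nodal signalling, was the 1 control-only gene of 28 (Fisher's exact test, adjusted p = 1). The region at CLDN4 lay on chromosome 3 from 11040650 to 11040856 and that at TDGF1 on chromosome 13 from 29538804 to 29539100, both inside the gene model. Control-only regions also lay at the ends of KAT8, a histone acetyltransferase, KLF4, UHRF2, SOX18 and PAX7, whose ends carried other peaks as well. Without BRG1 1 the imprinted list was called, with 3 of 19 genes (PEG10, SGCE and NNAT, named after their values were seen) having a gene-end peak in BRG1 4 and in neither control (adjusted p = 0.00692 by Fisher's exact test). PEG10 and SGCE shared 1 peak (chromosome 9, 74473807 to 74474008), and counting them once gave an adjusted p of 0.145 by Fisher's exact test, so the call rested on 1 library and a shared peak.

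Over all 19550 genes, 39 were BRG1-only and 104 control-only at their ends (exact binomial p = 5.18e-08), against 51 and 33, and 51 and 44, for the other splits. With lists of equal length the order turned, to 100 BRG1-only and 56 control-only genes (exact binomial p = 0.000534), of which 35 and 42 were the same genes as with all peaks. The binomial test takes both directions as equally likely and genes as independent, and with all peaks the control lists were longer. Neither p therefore tests an effect of BRG1. Leaving out control 1, control 4, BRG1 1 or BRG1 4 gave 100, 79, 149 and 121 BRG1-only and 214, 212, 345 and 195 control-only genes.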

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

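Several results depended on how many peaks each list held. With lists of equal length, the ratio of covered length turned to 1.06 and the gene-end difference to −0.0677, BRG1-only and control-only regions came to 2245 and 2240, and BRG1-only and control-only genes to 100 and 56; equal lengths hold the 2 region counts near each other by construction. With lists of 45425 peaks each the ratio was 1.1, control-only regions 1107 and the gene counts 105 and 44. Reciprocal overlap of 50% gave 1728 BRG1-only calls, counted as peaks of BRG1 1 and not as union regions. By that rule a control peak with a smaller overlap did not count as shared. A window of 3 kb, which lets peaks of control as well as BRG1 libraries reach more genes, gave 20 BRG1-only genes. What else moved these counts was not tested. Leaving out each library gave ranges of 2172 to 5308 BRG1-only regions, 8890 to 13217 control-only regions, 79 to 149 and 195 to 345 genes, 0.920 to 1.06 for the ratio of covered length, −0.0260 to 0.0790 for the Jaccard difference and 0 to 1 lists called (0 with imprinted genes that share a peak counted once, added after seeing the data), where fewer libraries had to share a call. The ratio of peak numbers lay between 0.851 and 0.903 under every alternative that was run for it. Replicate number as a block gave 0.877 for peak number, 0.986 for covered length and 1.09 for the gene-end difference (exact sign-flip p = 0.5, 1 and 0.5, the smallest possible being 0.5), and deviations of same-numbered libraries correlated at −0.0100 across regions. Thinning to the lowest depth, added after seeing the data, gave a peak ratio of 0.890, 1008.7 BRG1-only and 4644.2 control-only regions. The same minimum without thinning gave 0.875, 848 and 5312. In total 67 values kept their direction (counts within 1.5 times), 26 moved and 7 turned, but sizes differed among the 67: the gene-end difference was 0.0275 with lists of 45425 peaks. The motif comparisons were not run. Absolute depth is unknown, so a peak missing from a list means that it was not called at that depth, not that the region was closed.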

Other observations

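Genes outside the naming rule were chosen here after their values were seen. Among the 39 genes with a BRG1-only gene end were CXCL10, a chemokine, CIITA, the master activator of MHC class II genes, PDGFA, a growth factor for fibroblasts, LAMA5, a laminin chain, and TFPI, an inhibitor of coagulation. Among the 104 genes with a control-only gene end were FGF10 and SEMA3C, which encode secreted signals, TNFRSF11B, a decoy receptor, TXNRD1, a redox enzyme, and T, the older symbol of the mesoderm regulator TBXT, which the early embryo list had left unmatched.

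Distances to shared regions were taken as a description and were not tested. BRG1-only regions lay a median of 4171 bp from the nearest region called in all 4 libraries and control-only regions 8548 bp, with 213 of 903 (23.6%) and 500 of 5376 (9.30%) within 1 kb.

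The tests of enrichment at shared regions, and those of gene proximity and list length for the cytokine genes, were set before their results were seen. Thinning, the ratio with equal lists and the comparison near cytokine genes were chosen after the result was seen.

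Control-only regions outnumbered BRG1-only regions, 5376 to 903. With a −log10 p of at least 5 and no thinning the counts were 5312 and 848. Thinning to the lowest depth gave 4644.2 and 1008.7, or 4.60 control-only regions per BRG1-only region, so depth may account for part of the excess. BRG1 1, the library of lowest depth, held 95329 peaks, against 105339 in control 1 before thinning and at least 101203 over 10 draws. BRG1 4 kept at most 85800. The gaps that remained argue against depth as the whole cause. Median enrichment at shared regions was 13.2 in BRG1 1, not below control 1 (12.5) or control 4 (13.1), which argues against weaker enrichment of BRG1 1 at those regions. In BRG1 4 it was 10.3, below both, so weaker enrichment may account for calls missing in BRG1 4. The strongest peaks were left out, with 73176 regions kept in BRG1 1, 72439 in control 4 and 72276 in control 1, so the small margin over control 4 is not weighed. Shared regions hold a call in every library, so enrichment where BRG1 1 lacked a call was not measured. Leaving out a BRG1 library gave 8890 control-only and 4042 BRG1-only regions without BRG1 4, and 13217 and 5308 without BRG1 1. Control-only regions then needed a peak in both controls and none in the remaining BRG1 library. BRG1-only regions needed a peak in that library alone. Counts under such unlike rules cannot show whether the excess rests on 1 BRG1 library. Regions called in every library but 1 follow a like rule for each library. The missing library was BRG1 4 for 7785 of them, BRG1 1 for 3328, control 4 for 1474 and control 1 for 1255. Both BRG1 libraries thus lacked more of these calls than either control, BRG1 4 the most. The ratio of 0.998 with lists of equal length is held there by construction, so list length and fewer open regions in BRG1 cells cannot be told apart by it, and an effect of BRG1 itself stays open and untested.

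As a hypothesis, BRG1-over-expressing cells may open regions near genes of cytokines, chemokines, and interleukin and interferon receptors. Of 903 BRG1-only regions, 8 (0.886%) lay within 10 kb of an end of such a gene. The control-only count was 16 of 5376 (0.298%), with AMCF-II, IL1A and IL16 among the genes, and sets of the other splits had 0.166% to 0.727%. The 8 included regions within 1 kb of CXCL8, CXCL10, IFNGR2 and IL6. The others lay 2231 bp from IL18, 5174 bp from IL16, 8918 bp from TNFSF15 and 9844 bp from IL1A. That near IL1A lay inside the model of CKAP2L, and that near IL18 within 1 kb of TEX12. TNFRSF and chemokine receptors were outside the symbols used, so regions such as the control-only one at TNFRSF12A were not counted. The genes were chosen after IL6, CXCL8 and IFNGR2 had been seen among the named regions, and 2 definitions by symbol with 3 windows were tried (Fisher's exact p from 0.00307 to 0.0549, 0.0155 for the 160 genes and 10 kb weighed here), so none of these p-values is evidence for the hypothesis and adjustment over the 6 does not cover the choice of genes. Without the named regions the counts were 5 of 887 (0.564%) and 14 of 5355 (0.261%, Fisher's exact p = 0.175), which leaves the hypothesis open and unsupported. That BRG1-only share lay inside the range of the other splits, and regions called in all 4 libraries had 0.441%. Among regions within 10 kb of any gene end the share was 2.40 times as high in BRG1-only regions (Fisher's exact p = 0.0517). That ratio still holds the regions at IL6, CXCL8 and IFNGR2 that prompted the choice, so it leaves closeness to genes of any kind open. With lists of equal length the ratio was 1.44 (13 of 2245 against 9 of 2240, Fisher's exact p = 0.522), so the difference in list length may account for the pattern.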
